A study of Homo sapiens with 19 samples.

How the data were processed

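RNA was measured by sequencing of poly(A)-selected messenger RNA from HRGEC, cultured glomerular endothelial cells of the human kidney, used at passage 3 to 4. Per the labels' protocols, the cells were washed and then kept with 10% serum for 3 h. The serum came from people without lupus (HC), from patients with lupus nephritis (LN) in remission, or from LN patients in flare. A further group got flare serum with 5 µM L-sepiapterin (L-Sep), and these cells had L-Sep alone for 1 h before the serum was added. The labels do not say whether the other cultures were held for that extra 1 h or got a vehicle, and no group had L-Sep with HC serum. The labels also mention dishes with medium only, and these are not analysed here.

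The deposited table holds counts of reads per gene, as whole numbers for 58735 genes in 19 libraries. Reads were aligned with HISAT2 2.0.5 to hg38 and counted with featureCounts 1.5.0-p3, per the submitters' processing notes. The strand setting and the handling of reads that align in several places are not given in the sources used here, so antisense, overlapping and near-identical genes are reported as uncertain. Gene symbols, biotypes and coordinates came from GENCODE release 29 on hg38, in which 58735 of the gene IDs were found. All libraries carry the same batch label. Groups were taken from the labels: HC serum (n = 5), LN remission serum (n = 4, numbered 1, 2, 4 and 5), LN flare serum (n = 5) and LN flare serum with L-Sep (n = 5). The labels do not say that the libraries come from separate cultures or serum donors, so p-values measure only the spread between these samples, which could be technical. Total counts per library ran from 17499916 to 27399261. The 36 pairs of libraries within groups differed by a chi-square per degree of freedom of 2.53 to 20.94, so no pair of libraries was a duplicate.

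Genes were tested in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr by group, which left 16133 genes, and libraries were scaled by TMM. A quasi-likelihood F-test was fitted to all 4 groups together, with group means only, for 5 comparisons: flare against HC serum and L-Sep with flare serum against flare serum (main), and remission against HC serum, flare against remission serum, and L-Sep with flare serum against HC serum (secondary). Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. CPM values are counts normalised to depth with the TMM factors, computed from the deposited counts, and are given as mean ± SD. Log2 fold changes are given with a standard error (SE).

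Gene groups were tested with camera of limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Of 40 lists, 38 had at least 5 tested members. Camera asks whether a list moves against all other genes, and lists that share members are not independent of each other. Each list call was repeated with an estimated correlation and with fry, which asks whether the members move, on balance, in a single direction. Counts of members that passed are given after adjustment over all tested genes and, beside them, adjusted over the list alone. A list score is the mean over members of log2 CPM minus the mean of the HC libraries, compared between groups by a two-sided exact permutation test.

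The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, in each main comparison, up to 12 genes in each direction with the smallest p-values at a mean CPM of at least 1, up to 3 called members of each list, and 26 genes given by name in advance. In each secondary comparison it takes up to 5 genes in each direction, or the 5 with the smallest p-values where none passed. Some genes that the rule names are not reported here, and they stay in all tests and counts. The alternatives were RLE and upper quartile factors, no filter, a filter of CPM of at least 1 in at least 4 samples, DESeq2 1.42.0, limma voom with sample quality weights, a fit of only the 2 groups compared, a replicate block, and leaving out each library in turn. A correction for GC content and transcript length, alone and with the replicate block, was added after the data were seen. It removes the trend of each library with the GC content and length of the longest transcript, which were available for 16128 of the tested genes. It was applied to the tests of single genes, and no camera or fry test of lists was repeated with it.

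The steps were tested on simulated data with 200 changed genes, drawn from the means and library sizes of the real libraries. The changed genes were picked only from genes above a minimum mean CPM. The shares below therefore do not hold for genes with few counts, such as NOS3. Genes were drawn independently of each other, without GC and length trends between libraries, in a single run per comparison. At a log2 fold change of 0.25, the share of changed genes recovered was 46% for flare against HC serum (15942 genes tested) and 48% for L-Sep with flare serum against flare serum (15947). It was 50% for remission against HC serum (15939), 38% for flare against remission serum (15948) and 40% for L-Sep with flare serum against HC serum (15966). At 0.5 it was 96%, 96%, 94%, 94% and 94% in the same order, and at 1 and at 2 all changed genes were recovered in each comparison. These shares hold for 200 changed genes in a comparison. Where fewer genes change, the adjustment is stricter and the shares can be lower. Figures were drawn with matplotlib 3.10.9.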

Results

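Gene expression was measured in 19 libraries of HRGEC, the cells that line the filtering capillaries of the kidney, after 3 h with human serum. The groups were HC serum (n = 5), LN remission serum (n = 4), LN flare serum (n = 5) and LN flare serum with L-Sep (n = 5). L-Sep is a precursor that cells turn into tetrahydrobiopterin (BH4), the cofactor of nitric oxide synthase. Total counts per library ran from 18624140 to 26936715 with HC serum, from 22547726 to 27399261 with remission serum, from 21561957 to 25832267 with flare serum and from 17499916 to 24123696 with L-Sep. The mitochondrial genome supplied 1.098% ± 0.311 of counts with HC serum (SD, n = 5), 1.44% ± 0.225 with remission serum (n = 4), 1.32% ± 0.19 with flare serum (n = 5) and 0.552% ± 0.237 with L-Sep (n = 5). Fibronectin (FN1) supplied 3.90% ± 0.55, 3.95% ± 0.297, 4.23% ± 0.468 and 5.44% ± 0.504 of counts in the same order. In a principal component analysis of log2 CPM, L-Sep replicates 1 to 4 lay at 22.2 to 32.1 on the component with the largest share of variance. L-Sep replicate 5 lay at -3.73, among the libraries without L-Sep (-15.4 to 2.83).

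**Figure D1:**
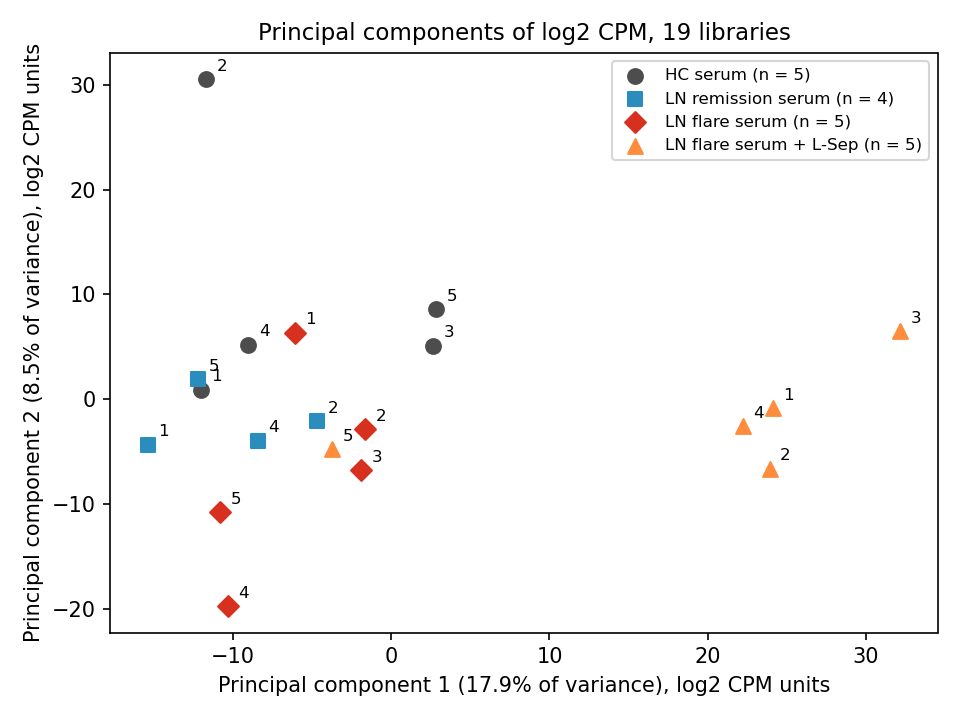
Scores of the 19 libraries on principal components 1 (17.9% of variance, x axis) and 2 (8.5%, y axis) of log2 CPM, coloured by group. L-Sep replicates 1 to 4 lie at 22.2 to 32.1 on component 1, L-Sep replicate 5 lies at -3.73, and HC replicate 2 is set apart on component 2 at 30.5.

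The comparison of flare with HC serum asks whether serum taken in a lupus flare changes these cells beyond control serum. At the level of single genes, 1 gene was higher and 4 were lower among 16133 tested. STK24 (ENSG00000102572, chromosome 13), a kinase of the STE20 family, was at 103 ± 2.65 CPM with flare serum and 85.5 ± 6.48 with HC serum (SD, n = 5 each, log2 fold change 0.27, SE 0.049), above the HC mean in 5 of 5 libraries. PIM3 (ENSG00000198355, chromosome 22), a kinase that promotes survival and growth, was at 57.2 ± 3.96 against 71.2 ± 3.5 CPM (-0.32, SE 0.0571). PTMS (ENSG00000159335, chromosome 12), which encodes the acidic nuclear protein parathymosin, was at 214.5 ± 11.2 against 252.0 ± 14.2 CPM (-0.23, SE 0.0416). MMP24OS (ENSG00000126005, chromosome 20) fell by 0.27 (SE 0.0459). It lies opposite MMP24, and without a stated strand setting its counts are uncertain. MAGED4B (ENSG00000187243, X chromosome) was at 1.69 ± 0.321 against 15.4 ± 15.1 CPM (-3.21, SE 0.53). It has a near-identical copy, MAGED4, which changed by 2.14 (SE 0.828), and the sum of both changed by -0.69 (SE 0.645), which is close to its SE, so this call is uncertain. All 5 genes had an edgeR adjusted p of 0.0471, 2216 genes had an unadjusted p under 0.05, DESeq2 called 240 genes (81 higher, 159 lower) and limma voom with sample weights 7 (6 higher, 1 lower, 2 of them shared with edgeR). The count was 0 without any of flare replicates 1, 2, 3, 4 or 5, 1 without HC replicate 4 or HC replicate 5, 6 without HC replicate 2 (4 higher, 2 lower), 30 without HC replicate 1 and 111 without HC replicate 3. After the correction for GC content and length, PTMS was at -0.11 (adjusted p 0.258), STK24 at 0.22 (0.13) and PIM3 at -0.23 (0.138), no longer called by edgeR, while MMP24OS at -0.24 (0.0036) and MAGED4B at -3.18 (0.0354) were.

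Between flare and HC serum, 8 gene lists moved by limma camera, and most members of each shared its direction. Of 33 tested type I interferon response genes, 32 were higher on average with flare serum, with a median log2 fold change of 0.88 (camera adjusted p 2.22e-06, adjusted p = 0.756 with an estimated correlation), and 0 members passed singly, also adjusted over the list alone. Its spread was wide: MX1, an antiviral GTPase, was at 27.96 ± 30.9 against 4.97 ± 2.78 CPM (SD, n = 5, edgeR adjusted p 0.21), IFIT1, an RNA-binding antiviral protein, at 26.5 ± 34.4 against 3.97 ± 2.13 (0.246), and ISG15, a ubiquitin-like protein, at 55.8 ± 34.0 against 36.4 ± 7.15 (0.428). The interferon score was 2.10 and 1.67 in flare replicates 2 and 3 and between -0.24 and 0.25 in the other 3. It differed by 0.78 between the groups (exact permutation p = 0.183, adjusted 0.451 over the lists), and by 0.45 without flare replicate 2. Of 34 cell cycle genes, 32 were higher (median 0.13, camera adjusted p 6.07e-12, adjusted p = 0.294 with an estimated correlation). None passed over all genes and 15 rose adjusted over the list alone. Mitochondrial encoded transcripts were higher for 13 of 13 members (median 0.30, camera adjusted p 0.000354, adjusted p = 0.756 with an estimated correlation). The interferon call was lost without flare replicate 2 (adjusted p 0.0514) and the mitochondrial call without HC replicate 5 (0.134), where the mitochondrial score difference was 0.16 and not 0.32.

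The other called lists were lower with flare serum. Genes of cytosolic ribosomal proteins were lower in 73 of 75 cases (median -0.13, camera adjusted p 1.45e-23, adjusted p = 0.593 with an estimated correlation), with 0 passing over all genes and 22 that fell adjusted over the list alone. Nuclear encoded genes of oxidative phosphorylation were lower in 61 of 63 cases (median -0.10, 1.06e-10, adjusted p = 0.756 with an estimated correlation, 0 adjusted over the list alone). Antioxidant enzymes outside the NRF2 programme were lower in 20 of 22 cases (median -0.11, 7.31e-07, adjusted p = 0.588 with an estimated correlation, 5 fell adjusted over the list alone). Lysosomal genes were lower in 17 of 24 cases (median -0.05, 0.00381, adjusted p = 0.593 with an estimated correlation, 3 fell adjusted over the list alone). NF-kB and inflammatory cytokine genes were lower in 24 of 32 cases (median -0.16, 0.0186, adjusted p = 0.939 with an estimated correlation, 1 fell adjusted over the list alone). HC replicate 2 had a ribosomal score of 0.205 (the other HC libraries -0.07 to -0.01), the lowest sample weight in its group (0.273) and the largest GC and length trend of all libraries (SD 0.146). Without it the ribosomal score difference was -0.07 and not -0.12, and that of oxidative phosphorylation -0.06 and not -0.10. Fold changes of this comparison ran with transcript length at a Spearman rho of 0.462 and with GC content at -0.371 over 9911 genes, which are not independent replicates. The calls of these lower lists were not repeated with the GC and length correction, so such a trend stays open for them. The NF-kB call was lost without HC replicate 5 (adjusted p 0.449, score difference -0.09 and not -0.18) and without flare replicate 1 (0.149). With an estimated correlation 0 lists were called, and with fry 1, the cell cycle list.

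The genes named in advance for this system did not pass between flare and HC serum, by edgeR. In the nitric oxide and BH4 pathway the log2 fold changes were -0.18 for NOS3 (endothelial nitric oxide synthase, SE 0.196) and -0.05 for GCH1 (which starts BH4 synthesis, SE 0.0873). They were -0.09 for SPR (which converts sepiapterin, SE 0.0735), -0.14 for PTS (a middle step of BH4 synthesis) and -0.03 for QDPR (which recycles BH4). Among inflammatory and adhesion genes they were -0.39 for the chemokine CCL2 (SE 0.131, adjusted p 0.198), -1.05 for SELE (E-selectin, SE 0.388), -0.25 for ICAM1, 0.02 for VCAM1, -0.25 for IL6 and 0.05 for CXCL8. Redox genes gave -0.34 for SOD2, -0.17 for NOX4, -0.04 for NQO1, -0.07 for HMOX1 and 0.06 for TXNIP. Without HC replicate 5, IL6 was at -0.01, SOD2 at -0.18, ICAM1 at -0.12, KLF2 at 0.08 and TSC22D3 at 0.07. Other libraries moved NOX4 (-0.04 without HC replicate 3, -0.11 without HC replicate 2, -0.10 without flare replicate 2, -0.27 without HC replicate 1), NOS3 (-0.10 without HC replicate 1, -0.08 without HC replicate 4), PTS (-0.07 without HC replicate 2) and ICAM1 (-0.40 without flare replicate 4). KLF2 was at 0.20 without HC replicate 3, 0.06 without HC replicate 4 and 0.07 without flare replicate 1, and TSC22D3 at 0.18 without flare replicate 2 and 0.02 without flare replicate 4. The remaining values were 0.13 for KLF2, 0.14 for FKBP5, 0.11 for TSC22D3 and 0.17 for HMGCS1. CXCL10 was below the filter. The nitric oxide and BH4 list was not called (median -0.03, camera adjusted p 0.767, with 1 that fell adjusted over the list alone). Of the 30 lists that were not called, those nearest to the threshold were the NRF2 antioxidant response (median -0.04, 3 fell adjusted over the list alone) and YAP and SRF cytoskeletal targets (median -0.06, 0 adjusted over the list alone), both at an adjusted p of 0.0503. Genes of purine synthesis followed at 0.0962 (median 0.05, with 3 that rose and 1 that fell adjusted over the list alone), and interferon gamma genes had 3 that fell adjusted over the list alone (median -0.06, adjusted p 0.44). Median, mean and test differed in sign for glycolysis, immediate early genes, cholesterol synthesis, lipid loading, the glucocorticoid response, endothelial identity, podocyte and mesangial markers, all with medians within 0.022 of 0.

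The comparison of L-Sep with flare serum against flare serum asks what the BH4 precursor changes in cells that get flare serum. With L-Sep, 960 genes were higher and 696 lower of 16133 (edgeR), mostly by small amounts. The median size of the log2 fold change was 0.26, and 74 genes changed by at least 2-fold. The L-Sep cultures also had 1 h with L-Sep alone before the serum. The labels do not give that hour or a vehicle for the other cultures, so these cannot be told apart from L-Sep itself. LBH (ENSG00000213626), a transcription cofactor, rose from 131 ± 7.08 to 201 ± 18.8 CPM (SD, n = 5 each, log2 fold change 0.62, SE 0.0643, edgeR adjusted p 3.31e-05). GUCY1A2 (ENSG00000152402), a subunit of the soluble guanylate cyclase that senses nitric oxide, rose from 8.14 ± 1.13 to 16.6 ± 2.66 CPM (1.03, SE 0.126, adjusted p 0.00011). GPER1, a membrane estrogen receptor, rose by 0.86, and PIK3IP1, an inhibitor of PI3 kinase, by 0.35. PSAT1 (ENSG00000135069) and PHGDH (ENSG00000092621), enzymes of serine synthesis, fell from 74.9 ± 2.28 to 58.8 ± 2.18 CPM (-0.35, SE 0.0373) and from 77.5 ± 2.58 to 61.8 ± 1.62 CPM (-0.33, SE 0.0405). The 12 genes with the smallest p-values among those higher had log2 fold changes of 0.27 to 1.03, and the 12 among those lower of -0.69 to -0.23. Each of these genes lay on its side of the flare mean in 5 of 5 L-Sep libraries. This follows largely from their choice by p-value in the same libraries. Of 2621 genes called without L-Sep replicate 5, that library lay beyond the flare range, on the L-Sep side, at 43.8%. HC and remission libraries did so at 11.2% to 45.1%, the highest being HC replicate 5. Chance would give 16.7% only for genes chosen without the flare libraries, and these were in the fit that chose the genes. Beside these results, the mitochondrial share of counts was 0.552% ± 0.237 with L-Sep and 1.32% ± 0.19 with flare serum (SD, n = 5).

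The count of 1656 genes called with L-Sep had 4131 genes at an unadjusted p under 0.05 behind it, and DESeq2 called 1874 genes and limma voom with sample weights 3060. It was 1099 without flare replicate 2, 1054 without flare replicate 5, 920 without L-Sep replicate 2, 993 without L-Sep replicate 3, 971 without L-Sep replicate 4 and 2621 without L-Sep replicate 5, the library that lay among those without L-Sep; leaving out flare replicate 1 gave 1105. The share of higher genes, 58%, was 47.3% (779 higher, 867 lower) with the filter at CPM of at least 1 48.7% (757 higher, 799 lower) with upper quartile factors, 45% (497 higher, 608 lower) without flare replicate 1 and 41.6% (1116 higher, 1568 lower) with the replicate block and the GC and length correction.

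**Figure D2:**
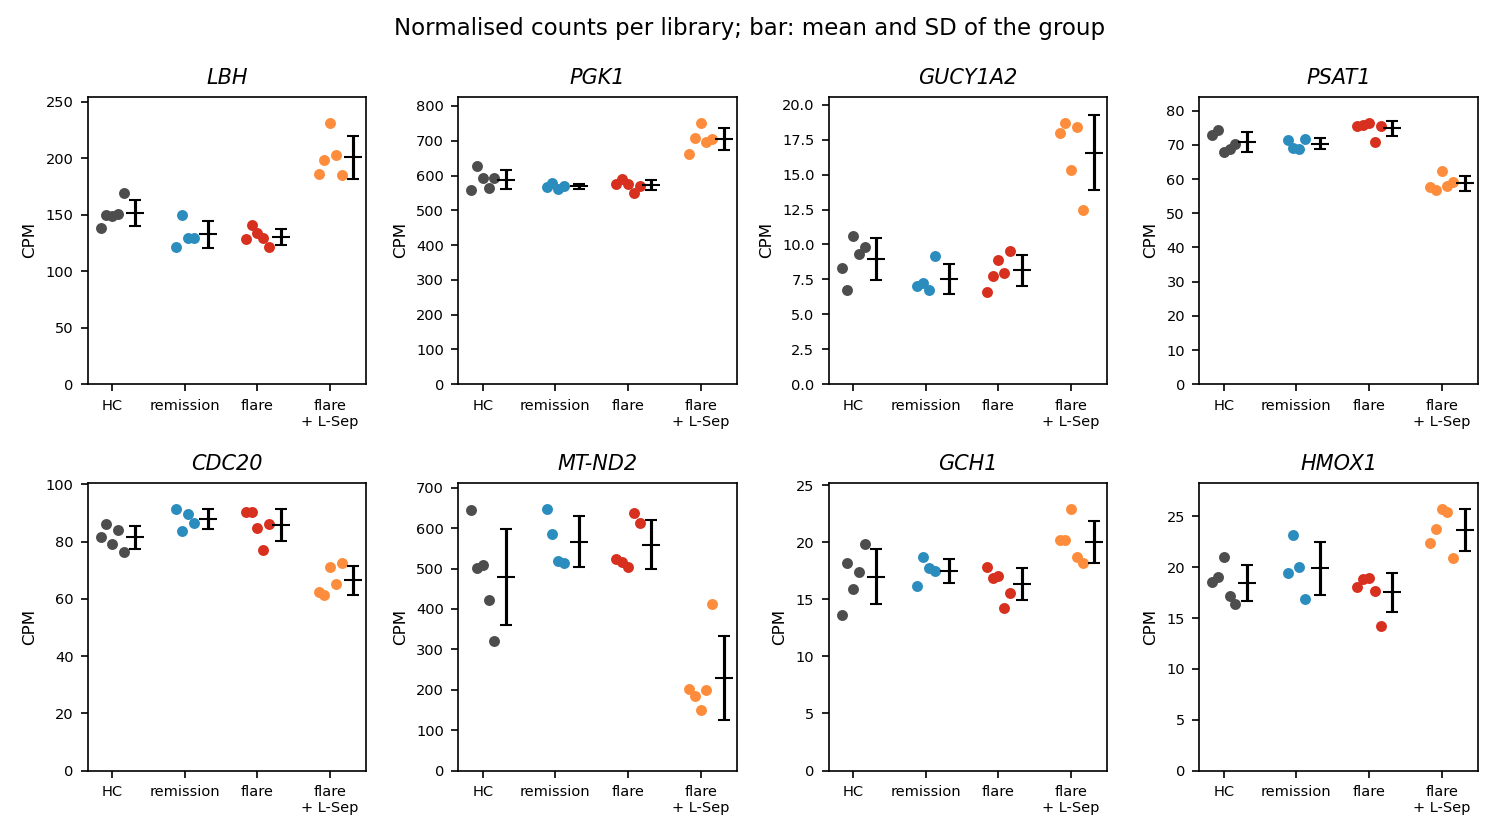
CPM per library (points) with the group mean and SD (bars) for genes named in the text, 1 panel per gene, with the groups on the x axis and CPM from 0 on the y axis. LBH is at 201 ± 18.8 CPM with L-Sep and 131 ± 7.08 with flare serum alone.

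Genes of cell division were lower with L-Sep. Of 34 cell cycle genes, 20 fell, 0 rose and 14 did not pass, and 29 fell adjusted over the list alone (median -0.20, camera adjusted p 8.67e-21, adjusted p = 0.0379 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 85.9 ± 5.45 to 66.5 ± 5.0 CPM (SD, n = 5, -0.37, SE 0.0522), and the replicative helicase subunits MCM5 and MCM4 fell by 0.24 and 0.24. Outside the list, TFDP1, a partner of E2F factors, fell by 0.23, TIMELESS, a replication fork protein, by 0.28, and LMNB1, lamin B1, by 0.32. Of 25 p53 targets, 5 fell and 1 rose, with 9 and 1 adjusted over the list alone (median -0.11, 0.00251, adjusted p = 0.188 with an estimated correlation). MDM2, the ubiquitin ligase that restrains p53, fell from 153 ± 8.16 to 115 ± 9.53 CPM (-0.42, SE 0.05), and AEN, an apoptosis nuclease, fell by 0.24. Of 20 genes of purine nucleotide synthesis, 3 fell and 0 rose, with 7 that fell adjusted over the list alone (median -0.05, 0.00425, adjusted p = 0.284 with an estimated correlation). These were PFAS (-0.29), GART (-0.20) and PAICS (-0.14), enzymes of de novo purine synthesis. Replication dependent histones did not pass, with 0 of 13 members called and 0 adjusted over the list alone (median 0.09, camera adjusted p 0.741). Only these 13 of 30 matched members passed the filter in the poly(A)-selected libraries, so the list says little about histone transcripts.

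Transcripts of the mitochondrial genome were the group with the largest median change with L-Sep, and genes of glycolysis and lysosomes were higher. All 13 mitochondrial encoded transcripts fell, also adjusted over the list alone (median -1.15, camera adjusted p 6.28e-21, adjusted p = 0.0798 with an estimated correlation). MT-ATP6, a subunit of ATP synthase, fell from 856 ± 143 to 306 ± 167 CPM (SD, n = 5, -1.48, SE 0.242), and the complex I subunits MT-ND2 and MT-ND3 fell by 1.29 and 0.95. L-Sep replicate 5 had 0.968% of its counts from the mitochondrial genome, and the group mean was 0.552%. Nuclear encoded genes of oxidative phosphorylation gave 0 calls of 63, 0 adjusted over the list alone (median 0.03, adjusted p 0.35). Of 33 glycolysis and hypoxia genes, 16 rose and 0 fell, with 19 and 2 adjusted over the list alone (median 0.13, 1.1e-07, adjusted p = 0.0798 with an estimated correlation). They include PGK1 (0.30, SE 0.0372) and ALDOC (0.44, SE 0.0661), both glycolytic enzymes, and P4HA1 (0.33, SE 0.0438), a hydroxylase of collagen prolines. Of 24 lysosomal genes, 9 rose and 0 fell, with 13 that rose adjusted over the list alone (median 0.10, 4.05e-07, adjusted p = 0.0798 with an estimated correlation). Among them were NPC2 (0.19), a cholesterol carrier, SQSTM1 (0.27), an autophagy receptor, and GABARAPL1 (0.32), a protein of autophagosome membranes.

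Inflammatory genes were higher with L-Sep than with flare serum alone, and type I interferon genes were not called. Of 32 NF-kB and cytokine genes, 10 rose and 0 fell, with 16 that rose adjusted over the list alone (median 0.37, camera adjusted p 2.48e-08, adjusted p = 0.376 with an estimated correlation). The chemokine CCL2 rose from 21.1 ± 3.58 to 30.8 ± 4.87 CPM (SD, n = 5, 0.55, SE 0.13, edgeR adjusted p 0.0116), CXCL6, a neutrophil attractant, by 0.51, and TNIP1, a feedback inhibitor of NF-kB, by 0.23. ICAM1 (0.48, adjusted p 0.0976), IL6 (0.47, 0.185), SELE (0.80, 0.206), CXCL8 (0.39, 0.27) and VCAM1 (0.15, 0.167) did not pass in edgeR, and without L-Sep replicate 4 SELE was at 0.47 and CXCL8 at 0.25. Of 21 interferon gamma and antigen presentation genes, 8 rose and 0 fell, with 9 and 1 adjusted over the list alone (median 0.16, 0.0111, adjusted p = 0.396 with an estimated correlation). They include HLA-B (0.34), which presents peptides, and GBP2 (0.57), a GTPase induced by interferon. Adhesion and leukocyte recruitment genes were not called, with 3 that rose and 1 that fell of 18, also adjusted over the list alone (median 0.16, camera adjusted p 0.117). Other tests did call them: their score differed by 0.17 (exact permutation p = 0.00794, adjusted 0.0377 over the lists), and limma fry gave an adjusted p of 0.0398, as 1 of 22 lists it called. By the same score test the NF-kB list (adjusted p 0.086) and the interferon gamma list (0.301) did not pass. Nor did other lists called by camera: TGF-beta response (0.113), glycolysis (0.0549), purine synthesis (0.086) and heat shock (0.23). Endothelial identity (0.168), podocyte markers (0.0549) and ribosomal proteins (0.537) did not pass either. The other lists called by camera passed at 0.0377. Of 33 type I interferon genes 0 passed, also adjusted over the list alone (adjusted p 0.35), with IFIT1 at 0.04 (SE 0.866), MX1 at -0.01 (SE 0.745) and ISG15 at 0.00 (SE 0.334). Beside these groups, the mitochondrial share of counts was 0.552% with L-Sep and 1.315% with flare serum.

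Lists of TGF-beta response, angiogenesis and cytoskeletal genes were called by camera as higher with L-Sep, with less than 50% of the members of each passing. Of 25 TGF-beta response genes, 9 rose and 0 fell, with 11 that rose adjusted over the list alone (median 0.16, camera adjusted p 1.68e-05, adjusted p = 0.366 with an estimated correlation). FN1, fibronectin, rose from 41840 ± 4880 to 56310 ± 6200 CPM (SD, n = 5, 0.43, SE 0.0958), and COL4A2, a chain of basement membrane collagen, by 0.20. FN1 takes a visible share of all counts, 5.44% ± 0.504 with L-Sep. Of 30 angiogenesis and VEGF response genes, 10 rose and 0 fell, with 13 and 1 adjusted over the list alone (median 0.15, 7.15e-05, adjusted p = 0.188 with an estimated correlation). They include TIMP3 (0.58, SE 0.0739), an inhibitor of metalloproteinases, and the metalloproteinases MMP2 (0.38, SE 0.0507) and MMP14 (0.17, SE 0.0337). Of 24 YAP and SRF targets, 7 rose and 0 fell, with 10 and 1 adjusted over the list alone (median 0.10, 0.000386, adjusted p = 0.312 with an estimated correlation). Of 16 heat shock genes, 5 fell and 0 rose, with 6 that fell adjusted over the list alone (median -0.04, 0.00425, adjusted p = 0.376 with an estimated correlation). The chaperones HSPD1 and HSPH1 fell by 0.18 and 0.17.

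Endothelial genes moved in both directions with L-Sep. Of 17 genes of the shear stress and KLF2 programme, 5 rose and 1 fell, with 9 and 2 adjusted over the list alone (median 0.14, camera adjusted p 0.0421, adjusted p = 0.25 with an estimated correlation). KLF2 itself, a transcription factor of quiescent endothelium, was the member that fell, from 27.6 ± 3.79 to 19.45 ± 3.64 CPM (SD, n = 5, -0.51, SE 0.119, edgeR adjusted p 0.0104), while CYP1B1, a cytochrome P450, rose by 0.95 and MEF2A, a factor upstream of KLF2, by 0.31. Of 23 endothelial identity genes, 8 rose and 1 fell, with 9 and 2 adjusted over the list alone (median 0.05, 0.0312, adjusted p = 0.376 with an estimated correlation). They include VWF, von Willebrand factor, from 57.5 ± 5.36 to 80.4 ± 7.77 CPM (0.48, SE 0.0768), the receptor TIE1 (0.19) and the transcription factor ERG (0.28). The KLF2 list was not called without flare replicate 4 (adjusted p 0.0678), flare replicate 5 (0.0518), L-Sep replicate 1 (0.0553) or L-Sep replicate 5 (0.0639). The identity list was not called without flare replicate 4 (0.0854), flare replicate 5 (0.0688), L-Sep replicate 3 (0.0668) or L-Sep replicate 5 (0.0614). Markers of another glomerular cell, the podocyte, were called with 3 that rose of 8, also adjusted over the list alone (median 0.11, 0.0264, adjusted p = 0.188 with an estimated correlation, 0.0534 without L-Sep replicate 5). NES, nestin, rose by 0.23 among them. Ribosomal protein genes were called with 0 of 75 passing singly, also adjusted over the list alone (median 0.04, 0.0266, adjusted p = 0.843 with an estimated correlation). That call was lost without flare replicate 4 (0.955, score difference 0.004 and not 0.041), flare replicate 5 (0.103), L-Sep replicate 2 (0.0529), L-Sep replicate 3 (0.0918) or L-Sep replicate 5 (0.0614).

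**Figure D3:**
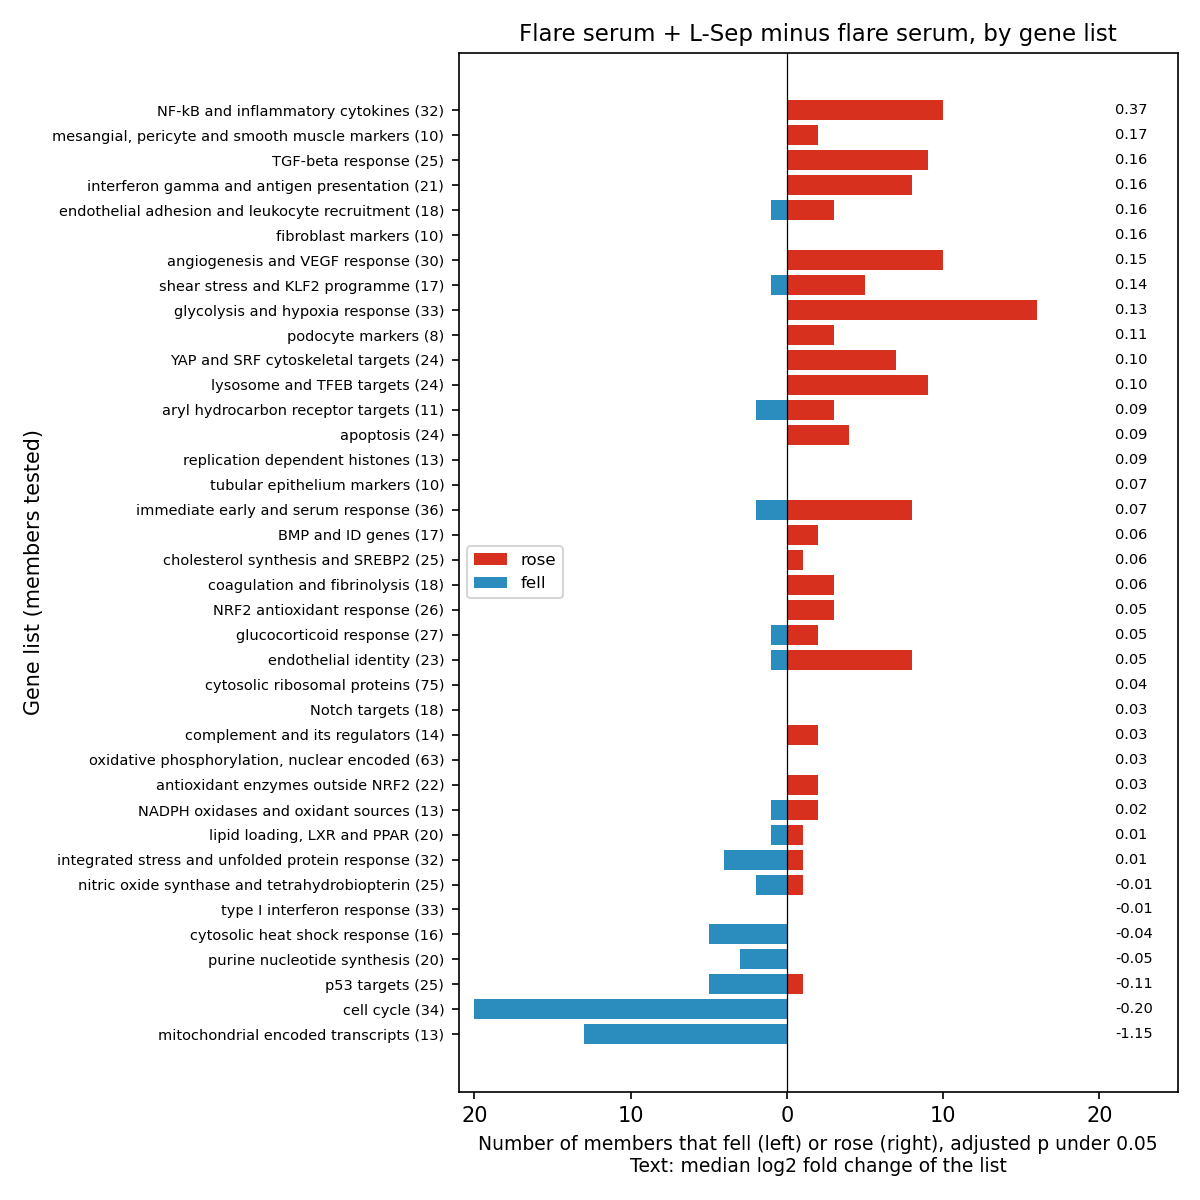
Number of members of each gene list that rose (right) or fell (left) with L-Sep and flare serum against flare serum, at an edgeR adjusted p under 0.05; the number of tested members stands beside each list name on the y axis and the text gives the median log2 fold change. The bars show 20 of 34 cell cycle genes and 13 of 13 mitochondrial transcripts that fell, and 16 of 33 glycolysis genes that rose.

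The lists of the BH4 pathway and of redox control were not called by camera with L-Sep. The nitric oxide and BH4 list was not called: 1 of 25 members rose and 2 fell, also adjusted over the list alone (median -0.01, mean 0.01, test direction down, camera adjusted p 0.619). HSP90AA1, a chaperone of nitric oxide synthase, fell by 0.15 (SE 0.0333, edgeR adjusted p 0.00647). GCH1 rose from 16.3 ± 1.4 to 20.1 ± 1.84 CPM (SD, n = 5, 0.29, SE 0.0867, adjusted p 0.0342). The GCH1 call was lost without flare replicates 2, 3, 4 or 5 or L-Sep replicates 1, 2 or 3, each taken out alone, with adjusted p of 0.0557 to 0.112. NOS3 (-0.19, SE 0.204, and -0.39, -0.09 and -0.10 without L-Sep replicates 1, 3 and 5), SPR (-0.01), PTS (-0.04) and QDPR (-0.04) did not pass. Of 26 NRF2 targets 3 rose and 0 fell, also adjusted over the list alone (median 0.05, camera adjusted p 0.205, and higher by fry at 0.0374), with HMOX1, heme oxygenase, from 17.5 ± 1.94 to 23.7 ± 2.05 CPM (0.43, SE 0.0887, adjusted p 0.00463) and NQO1 at -0.04. Of 22 antioxidant enzymes outside NRF2, 2 rose, also adjusted over the list alone (median 0.03, 0.278), and SOD2 was at 0.27 (0.24). Among 13 NADPH oxidase and oxidant source genes 2 rose and 1 fell, with 2 and 2 adjusted over the list alone (median 0.02, mean 0.08, test direction down, 0.929). NOX4 rose by 0.48 (adjusted p 0.0235), a call lost without flare replicate 1, flare replicate 2, L-Sep replicate 3 or L-Sep replicate 4 (0.0552 to 0.0929). TXNIP, an inhibitor of thioredoxin, was at -0.06.

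The remaining lists were not called by camera between L-Sep with flare serum and flare serum, but limma fry called 5 of them as higher: apoptosis (adjusted p 0.0149), mesangial and smooth muscle markers (0.0237), coagulation (0.0257), aryl hydrocarbon receptor targets (0.0398) and fibroblast markers (0.0438). Coagulation genes had 3 of 18 that rose (5 adjusted over the list alone), including the protease receptor F2RL1 (0.27). Complement genes had 2 of 14 that rose (2 adjusted over the list alone), including the regulator CLU (0.26). Apoptosis genes had 4 of 24 that rose (6 adjusted over the list alone), including CFLAR, a caspase 8 inhibitor (0.31). Immediate early genes had 8 that rose and 2 that fell of 36 (10 and 2 adjusted over the list alone), with EGR3 at 1.55, HBEGF at 0.42 and BTG2, an inhibitor of proliferation, at -0.40. Stress and unfolded protein response genes had 1 that rose and 4 that fell of 32 (2 and 4 adjusted over the list alone, median 0.01, mean 0.02, test direction down). Aryl hydrocarbon receptor targets had 3 and 2 of 11, also adjusted over the list alone, with the growth factor EREG at -0.47. Cholesterol synthesis had 1 of 25 that rose, also adjusted over the list alone, and HMGCS1, which did not pass, was at 0.17 (adjusted p 0.102). Lipid loading had 1 that rose and 1 that fell of 20, also adjusted over the list alone, with the lipid exporter ABCA1 at 0.47. Glucocorticoid response genes had 2 and 1 of 27, also adjusted over the list alone, with FKBP5 at -0.04, TSC22D3 at 0.04 and the editing enzyme ADARB1 at -0.30. BMP and ID genes had 2 of 17 that rose (2 and 1 adjusted over the list alone), and Notch targets 0 of 18, also adjusted over the list alone. Mesangial and smooth muscle markers had 2 of 10 that rose (3 adjusted over the list alone), fibroblast markers 0 of 10 (2 adjusted over the list alone) and tubular epithelium markers 0 of 10, also adjusted over the list alone. The leukocyte and the erythroid and platelet lists had too few tested members for a test. In the leukocyte list, LCP1 was at 0.55 (edgeR adjusted p 0.0345) and CORO1A at -0.36 (0.0164). The LCP1 call was lost in 8 of 10 fits with 1 library left out (without flare replicates 1, 2, 4 or 5 or L-Sep replicates 1, 2, 3 or 4, at 0.0515 to 0.115) and the CORO1A call without L-Sep replicate 2 (0.0507).

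With remission serum against HC serum, 0 genes passed by edgeR, with 1307 at an unadjusted p under 0.05; DESeq2 called 23 and limma voom with sample weights 2. The genes with the smallest p-values, which did not pass, were ANKRD18A at 3.70 ± 0.391 against 2.29 ± 0.377 CPM (SD, n = 4 and 5, 0.70, SE 0.128), CCBE1, a lymphatic growth protein, at 0.30 (SE 0.0575), EVPL, a plakin, at 0.34 (SE 0.0601) and MAGED4B at -2.87 (SE 0.554), all at an adjusted p of 0.123. HK2, hexokinase 2, was at 0.30 (SE 0.0623, adjusted p 0.158). The count was 10 without HC replicate 1 and 1 without HC replicate 2, HC replicate 4 or HC replicate 5.

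Among gene lists, 10 moved between remission and HC serum by camera, and 0 did with an estimated correlation. Mitochondrial encoded transcripts were higher in 13 of 13 cases (median 0.46, adjusted p 1.52e-09, adjusted p = 0.699 with an estimated correlation, 3 rose adjusted over the list alone). Cell cycle genes were higher in 29 of 34 (median 0.10, 5.24e-08, adjusted p = 0.486 with an estimated correlation, 5 rose adjusted over the list alone). Aryl hydrocarbon receptor targets were higher in 8 of 11 (median 0.39, 0.00139, adjusted p = 0.0926 with an estimated correlation, 4 rose adjusted over the list alone), the list that fry called too. Type I interferon genes were higher in 31 of 33 (median 0.38, 0.0215, adjusted p = 0.823 with an estimated correlation), and cholesterol synthesis genes in 19 of 25 (median 0.06, 0.0142, adjusted p = 0.806 with an estimated correlation), both with 0 adjusted over the list alone. Lower were ribosomal protein genes (median -0.07, 2.19e-08, adjusted p = 0.806 with an estimated correlation) and YAP and SRF targets (median -0.06, 0.00506, adjusted p = 0.797 with an estimated correlation, 4 fell adjusted over the list alone). Also lower were nuclear oxidative phosphorylation genes (median -0.04, 0.0142, adjusted p = 0.823 with an estimated correlation), antioxidant enzymes outside NRF2 (median -0.04, 0.0185, adjusted p = 0.797 with an estimated correlation) and lysosomal genes (median -0.04, 0.0221, adjusted p = 0.797 with an estimated correlation), with 0 passing adjusted over the list alone, as for the ribosomal list. Calls were lost without HC replicate 1 (interferon 0.0735, cholesterol 0.234), HC replicate 2 (antioxidant and oxidative phosphorylation 0.575, ribosomal 0.25, lysosome 0.0661), HC replicate 3 (interferon 0.105) and HC replicate 5 (YAP and lysosome 0.0825). They were also lost without remission replicate 1 (interferon and YAP 0.0791), remission replicate 2 (interferon 0.534, antioxidant, oxidative phosphorylation and cholesterol 0.0633) and remission replicate 5 (lysosome 0.101). Without HC replicate 2 the score difference of oxidative phosphorylation was 0.01 and not -0.03, that of ribosomal genes 0.00 (-0.002) and not -0.05, and that of antioxidant enzymes -0.02 and not -0.06. Without remission replicate 2 that of interferon genes was 0.11 and not 0.38. For YAP and SRF targets it was -0.03 without HC replicate 5 or remission replicate 1 and not -0.05, and for cholesterol synthesis 0.03 without HC replicate 1 and not 0.05. Among uncalled lists, median, mean and test differed in sign for NF-kB genes, complement, glycolysis, the stress response, immediate early genes and Notch targets.

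Between flare and remission serum, the comparison of the disease states, 0 genes passed by edgeR, with 1523 at an unadjusted p under 0.05; DESeq2 and limma voom with sample weights also called 0. The genes with the smallest p-values, which did not pass, were CA13, a carbonic anhydrase, at 8.48 ± 0.414 against 6.05 ± 0.566 CPM (SD, n = 5 and 4, 0.48, SE 0.0901), EHBP1L1 at -0.20 (SE 0.0429), TMED1 at -0.34 (SE 0.0704) and XYLT2, a xylosyltransferase, at -0.26 (SE 0.0535), all at an adjusted p of 0.294, and CCDC8 at -0.32 (SE 0.073, 0.446). By camera 4 lists moved. Ribosomal protein genes were lower (median -0.05, 2.18e-06, adjusted p = 0.854 with an estimated correlation), as were nuclear oxidative phosphorylation genes (median -0.07, 0.000182, adjusted p = 0.854 with an estimated correlation) and antioxidant enzymes outside NRF2 (median -0.05, 0.025, adjusted p = 0.854 with an estimated correlation, 1 fell adjusted over the list alone). Type I interferon genes were higher in 30 of 33 cases (median 0.53, 0.0307, adjusted p = 0.854 with an estimated correlation). Apart from that antioxidant gene, 0 members passed adjusted over the list alone. Without flare replicate 4 the ribosomal (0.106), oxidative phosphorylation (0.109) and antioxidant (0.178) calls were lost, and the interferon call was lost without remission replicate 4 (0.0795), remission replicate 5 (0.464), flare replicate 2 (0.91) or flare replicate 3 (0.598). The interferon score difference of 0.404 was 0.074 without flare replicate 2, 0.183 without flare replicate 3 and 0.175 without remission replicate 5. Without flare replicate 4 that of ribosomal genes was -0.03 and not -0.07, and that of oxidative phosphorylation -0.04 and not -0.07. Across genes, fold changes in this comparison ran with GC content at a Spearman rho of -0.631 over 9911 genes, which are not independent replicates. The list calls were not repeated with the GC and length correction, so such a trend stays open for them.

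Between L-Sep with flare serum and HC serum, which asks what differs from control serum when L-Sep is present, 1278 genes were higher and 892 lower (edgeR). The adenylate kinase AK4 rose from 81.0 ± 3.29 to 106.7 ± 3.46 CPM (SD, n = 5 each, 0.40, SE 0.0375, adjusted p 6.45e-06), and the sorting nexin SNX9 (0.40), the inhibitor TIMP3 (0.64), LHFPL2 (0.33) and the collagen hydroxylase P4HA1 (0.37) rose as well. CTIF, a translation factor, fell from 73.9 ± 4.51 to 52.8 ± 2.87 CPM (-0.48, SE 0.0496), and the serine synthesis enzymes PHGDH and PSAT1 fell by 0.40 and 0.27. IGFBP3, a carrier of insulin-like growth factors, fell by 0.33 and the splicing factor RBM10 by 0.27. The mitochondrial share of counts was 0.552% ± 0.237 with L-Sep and 1.098% ± 0.311 with HC serum (SD, n = 5). With upper quartile factors 1033 genes were higher and 1148 lower (47.4% higher against 58.9%), and the count of 2170 was 957 in a fit of these groups alone, 273 with the replicate block and 564 with the block and the GC and length correction. It was 1415 without HC replicate 4, 1440 without L-Sep replicate 2, 1437 without L-Sep replicate 3 and 1424 without L-Sep replicate 4.

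Of the lists, 16 moved between L-Sep with flare serum and HC serum by camera, and 0 did with an estimated correlation. Mitochondrial transcripts fell in 12 of 13 cases (13 adjusted over the list alone, 1.77e-12, adjusted p = 0.297 with an estimated correlation), p53 targets in 11 of 25 with 1 that rose (12 and 1 adjusted over the list alone, 9.81e-05, adjusted p = 0.224 with an estimated correlation) and cell cycle genes in 6 of 34 with 2 that rose (12 and 2 adjusted over the list alone, 7.7e-05, adjusted p = 0.379 with an estimated correlation). Ribosomal protein genes fell in 4 of 75 (3 adjusted over the list alone, 1.11e-06, adjusted p = 0.575 with an estimated correlation), nuclear oxidative phosphorylation genes in 4 of 63 (0 adjusted over the list alone, 5e-04, adjusted p = 0.575 with an estimated correlation) and heat shock genes in 4 of 16 (6 adjusted over the list alone, 0.00221, adjusted p = 0.454 with an estimated correlation). Antioxidant enzymes outside NRF2 had 1 that rose and 2 that fell of 22 (1 and 3 adjusted over the list alone, test direction down, 0.019, adjusted p = 0.57 with an estimated correlation). Glycolysis genes rose in 14 of 33 (17 adjusted over the list alone, 1.11e-06, adjusted p = 0.224 with an estimated correlation), TGF-beta genes in 8 of 25 (12 adjusted over the list alone, 0.000306, adjusted p = 0.47 with an estimated correlation) and angiogenesis genes in 5 of 30 (9 adjusted over the list alone, 0.000306, adjusted p = 0.298 with an estimated correlation). NF-kB genes rose in 6 of 32 (6 adjusted over the list alone, 0.00104, adjusted p = 0.575 with an estimated correlation), fibroblast markers in 4 of 10 (7 adjusted over the list alone, 0.00817, adjusted p = 0.298 with an estimated correlation) and lysosomal genes in 3 of 24 (5 adjusted over the list alone, 0.00898, adjusted p = 0.418 with an estimated correlation). Type I interferon genes had 1 of 33 that rose (0 adjusted over the list alone, 0.0183, adjusted p = 0.644 with an estimated correlation), the KLF2 programme 4 that rose and 1 that fell of 17 (6 and 1 adjusted over the list alone, 0.0183, adjusted p = 0.297 with an estimated correlation) and podocyte markers 2 of 8 that rose (4 adjusted over the list alone, 0.0341, adjusted p = 0.298 with an estimated correlation). Calls were lost without HC replicate 2 (antioxidant 0.135, oxidative phosphorylation 0.107, podocyte 0.0983), HC replicate 3 (interferon 0.066) and HC replicate 5 (podocyte 0.0624). They were also lost without L-Sep replicate 2 (interferon 0.397), L-Sep replicate 3 (interferon 0.0954, podocyte 0.0527) and L-Sep replicate 5 (antioxidant 0.0699, podocyte 0.0698). Score differences without HC replicate 2 were -0.03 and not -0.08 for ribosomal genes, -0.02 and not -0.07 for oxidative phosphorylation and -0.06 and not -0.09 for antioxidant enzymes. That of interferon genes was 0.41 and not 0.74 without L-Sep replicate 2, and that of NF-kB genes 0.155 and not 0.236 without L-Sep replicate 3. Among uncalled lists, median, mean and test differed in sign for NRF2 targets and for lipid loading.

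The 4 genes that fell with flare serum against HC serum included 2 that rose with L-Sep: MMP24OS by 0.18 (edgeR adjusted p 0.0186) and PTMS by 0.15 (0.022). Both comparisons use the same flare libraries, which by itself moves such genes opposite ways. PIM3 was at 0.17 (0.0586) and STK24 at -0.10 (0.19). Across all 16133 genes, the fold changes of L-Sep and of flare serum had a Pearson r of -0.363 (Spearman rho -0.289), and 50 simulations of unchanged groups that share the flare libraries gave a mean r of -0.485. The covariance was -0.0191 against -0.0145 simulated, a difference of -0.00459, and with the flare libraries split between the comparisons r was -0.05. For remission and flare serum against HC serum r was 0.563 (rho 0.491) against 0.488 simulated. The covariance was 0.0233 against 0.0153, a difference of 0.00802, and r was 0.117 with the HC libraries split. Genes are not independent replicates in these correlations. Genes higher with L-Sep against flare serum and against HC serum shared 573 members (76 in independent lists), genes lower shared 345 (38.5), and 0 went opposite ways (53.1 and 55.1); both comparisons use the same L-Sep libraries.

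**Figure D4:**
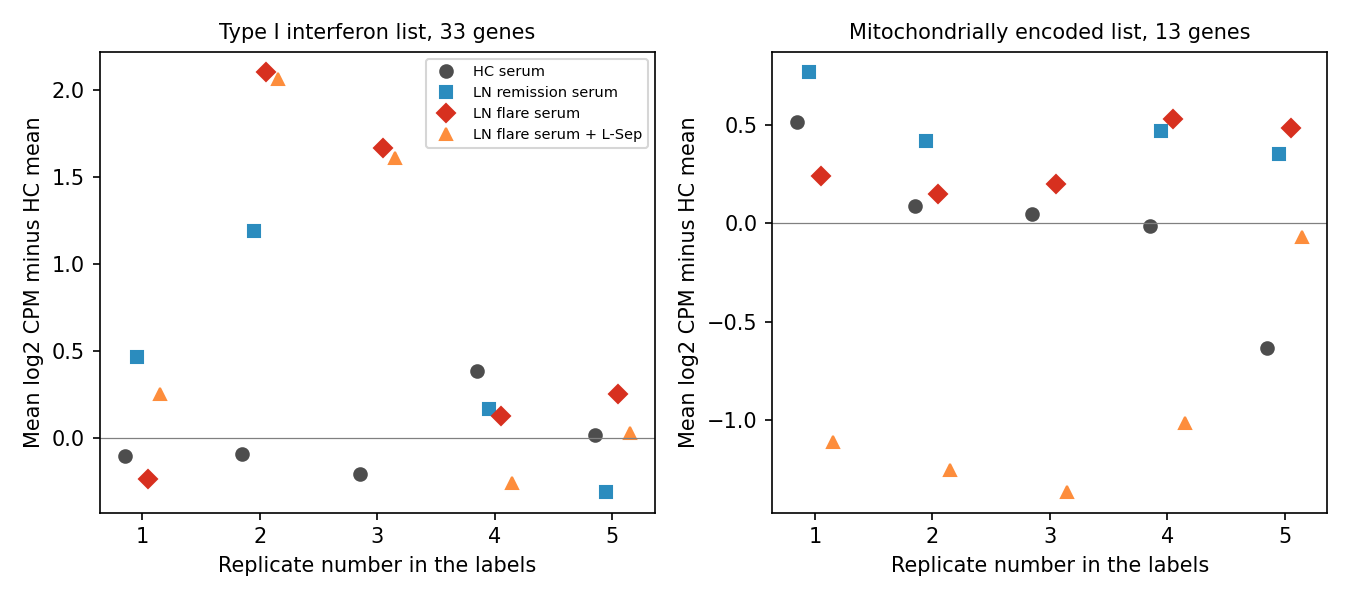
Scores per library for gene lists, as mean log2 CPM minus the HC mean (y axis), against the replicate number in the labels (x axis), coloured by group. The type I interferon score is 2.10 and 1.67 in flare replicates 2 and 3, 2.06 and 1.61 in L-Sep replicates 2 and 3, and between -0.26 and 0.25 in the other libraries of those groups.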

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

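The rule for a library far from the others of its group was fixed before the values were seen, and the tests in the last paragraph here were chosen after them, with the count of lists and the look at single noncoding RNAs added after a first form of each test had been read as a decision. The rule, Dixon's test at 0.05 within each group, was applied to 708 sets of values: shares of counts, list scores, and CPM of the named genes. It marked 42, where chance alone gives about 35 (1 in 20), so most marks are what chance would leave. They fell on 13 sets with HC serum, 5 with remission serum, 11 with flare serum and 13 with L-Sep.

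With HC serum, replicate 5 stood out in inflammatory genes, with 73.4 CPM of SELE (E-selectin), 236 of SOD2, 30.8 of the cytokine IL6, 55.3 of the NF-kB target BIRC3, and an immediate early score of 0.123. Replicate 2 had a ribosomal protein score of 0.205, 117 CPM of NQO1, 44.6 of VWF and 114 of NPC2. Replicate 3 had 84.8 CPM of MCM4 and 166 of F2RL1, and replicate 1 had 143 CPM of the collagen hydroxylase P4HA2. With remission serum, replicate 2 had 21.3 CPM of the interferon gene IFIT1, replicate 4 had 61.8 CPM of VWF and 0.629 CPM of EGR3, replicate 1 had 1.77% of its counts from the mitochondrial genome, and replicate 5 had an interferon gamma score of -0.037.

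With flare serum, replicate 4 stood out most often, with 215 CPM of the chemokine CXCL8, 70.8 of PSAT1, 23.7 of PIK3IP1, 59.3 of MCM5, 28.8 of the transcription factor FOXO1, 433 of the thrombin receptor F2R and 504 of the complement regulator CD59. Replicate 5 had 14.2 CPM of HMOX1 and 4120 of COL4A2, replicate 1 had 3.8 CPM of GPER1, and replicate 2 had a glycolysis score of 0.039. With L-Sep, replicate 3 had an angiogenesis score of 0.305, an endothelial identity score of 0.132, 56.6 CPM of MCM5 and 3.12 of LCP1. Replicate 4 had 89.2 CPM of NES and 42.9 of CCBE1, and replicate 1 had a glycolysis score of 0.032.

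L-Sep replicate 5 stood out in mitochondrial transcripts, with 412 CPM of MT-ND2, 601 of MT-ATP6, 149 of MT-ND3, a mitochondrial score of -0.071 and a mitochondrial share of 0.968% of counts. The other L-Sep libraries had mitochondrial shares of 0.389% to 0.496%. Some nuclear noncoding RNAs followed the same pattern: MEG3 was at 149 to 177 CPM in L-Sep replicates 1 to 4, 448 in replicate 5 and 293 to 531 with flare serum, and NEAT1 at 71.1 to 109 CPM against 201 in replicate 5. In serine synthesis replicate 5 was like the other L-Sep libraries, with 60.1 CPM of PHGDH and 59.3 of PSAT1. Both genes were named for their small p-values in a fit that included replicate 5, so this likeness follows largely from their choice.

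Whether L-Sep replicate 5 got no L-Sep could not be decided: of 2621 genes called without it, it lay beyond all 14 libraries without L-Sep at 20.6%, against 69.4% to 72.9% for L-Sep replicates 1 to 4, 20.8% for the highest of 9 HC and remission libraries and 6.7% by chance. Of 13 lists it lay beyond those 14 libraries in 6, against 8 to 10 for L-Sep replicates 1 to 4 and at most 4 for a library without L-Sep, and the share of these lists beyond the flare range, an earlier form of this test, was 0.615 (0.538 for HC replicate 5). L-Sep replicates 1 to 4 were in the fit that chose these genes and lists, which raises their values, and L-Sep replicate 5 was not. The flare libraries were in that fit too, so 6.7% would be the chance value only for genes chosen without them. A swap with flare replicate 5 is not favoured, since that library carried a share of 0.075 of the L-Sep profile, the lowest of the flare libraries (0.075 to 0.247), where L-Sep replicates 1 to 4 had 0.864 to 0.997; replicate 5 had 0.185, inside the flare range, so less L-Sep or a weaker response stays open. For the fall of mitochondrial transcripts, a loss of nuclear and mitochondrial RNA in extraction stays open: 12 nuclear long noncoding RNAs, listed after MALAT1 and KCNQ1OT1 had been seen not to follow, had a median log2 fold change of -0.11 (-0.108 ± 0.088, SE), but MEG3 (-0.81, edgeR adjusted p 0.0303) and GAS5 (-0.23, 0.0372) fell, and NEAT1 (-0.55), MALAT1 (0.30) and KCNQ1OT1 (0.50) did not pass. The GC and length trend is not favoured, with a ratio of 1.02 after the correction to before, while lower recovery of mitochondria alone or a biological fall in their transcripts stays possible.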

How the results depend on the processing

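Alternatives were listed before the data were examined, except the GC and length correction, alone and with the replicate block, which was added after. Of the named genes called in the comparison of L-Sep with flare serum against flare serum, 69 of 100 were called in all settings, among them LBH, PSAT1, GUCY1A2, MDM2 and FN1. For L-Sep with flare serum against HC serum it was 10 of 10, and for flare against HC serum 0 of 5. Those 10 had the smallest p-values in their direction, so this does not extend to the other calls of that comparison. Of its 2170 called genes, 955 stayed called with only the 2 groups and 272 with the replicate block. The 100 genes were also picked mostly by small p-values, overall or within a list. Their share of 69 therefore does not extend to all 1656 calls between L-Sep with flare serum and flare serum. Of those 1656, 902 stayed called without L-Sep replicate 2. No named gene that was called changed direction.

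Between flare and HC serum the count of 5 genes was 116 without a filter, 240 with DESeq2, 0 with only the 2 groups, 0 with the replicate block and 1 with the block and the GC and length correction. It ran from 0 to 111 when 1 library was left out. The 8 lists were 0 with an estimated correlation and 1 with fry. A fit of 2 groups has fewer libraries to estimate the spread, and the cause of the other changes was not tested.

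Between L-Sep with flare serum and flare serum, the 1656 genes were 3060 with voom and sample weights, which gave L-Sep replicate 5 a weight of 0.458, and 2684 with the block and the GC and length correction. They ran from 920 to 2621 when 1 library was left out. The 16 lists were 1, the cell cycle list, with an estimated correlation. The cause was not tested, except that an estimated correlation asks more of lists whose members move together.

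Between remission and HC serum the 0 genes were 44 without a filter, 23 with DESeq2, 2 with voom and sample weights and 2 with the block and the GC and length correction, and ran from 0 to 10 when 1 library was left out. The 10 lists were 0 with an estimated correlation, 1 with fry, and 6 to 12 when 1 library was left out. Between flare and remission serum the 0 genes were 3 without a filter, 3 with the block and 1 with the block and the GC and length correction. The 4 lists were 0 with an estimated correlation, 0 with fry, 9 with the block, and 3 to 8 when 1 library was left out. Between L-Sep with flare serum and HC serum the 2170 genes were 957 with only the 2 groups, 273 with the block and 564 with the block and the GC and length correction, and ran from 1415 to 3069 when 1 library was left out. The 16 lists were 0 with an estimated correlation. For these changes the cause was not tested.

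The correlation of L-Sep and flare fold changes was -0.196 over genes with a mean CPM of at least 10 and -0.05 with the flare libraries split, and that of remission and flare fold changes was 0.117 with the HC libraries split. When 1 library was left out they ran from -0.425 to -0.304 and from 0.486 to 0.635. The split removes the shared libraries, and by construction the part of the correlation that they add. The covariance left was -0.00336 for L-Sep and flare fold changes and 0.00692 for remission and flare fold changes. The observed covariances less the simulated ones were -0.00459 and 0.00802.

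The results that reversed were not called. Between flare and HC serum, SPR was at 0.01 with the GC and length correction and 0.01 with the block added, and HMOX1 at 0.01 and 0.01. QDPR was at 0.01 with voom and sample weights, 0.03 with the GC and length correction and 0.03 with the block added, and VCAM1 at -0.01 with the GC and length correction. With 1 library left out, GCH1 ran from -0.13 to 0.01, VCAM1 from -0.02 to 0.07 and CXCL8 from -0.08 to 0.20. With L-Sep, IFIT1 was at -0.28 with voom and sample weights. IFIT1 ran from -0.91 to 0.99, MX1 from -0.79 to 0.74, PTS from -0.08 to 0.01, TSC22D3 from -0.10 to 0.13 and SPR from -0.09 to 0.04 when 1 library was left out. The cause was not tested.

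The labels do not say that equal numbers mark paired samples. Over all tested genes, libraries of flare serum and of L-Sep with the same number correlated at 0.091 to 0.17 after group means were removed. Over genes outside the interferon lists no other of 120 pairings gave a higher sum, a share of 0.00833. A shared serum or a shared culture day would give this, and the lowest value is under the limit of 0.1 set before the data were examined. With HC libraries of the same number, correlations were -0.028 to 0.052 for flare, -0.041 to 0.062 for remission and -0.165 to 0.057 for L-Sep. Flare and remission libraries of the same number correlated at -0.03 to 0.132. With the block, 2053 genes were called between L-Sep with flare serum and flare serum. Depth limits the genes with few counts: NOS3 had 1.79 to 2.31 CPM in its group means, and CXCL10 fell below the filter.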

Other observations

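The tests in this part were chosen after the results were seen, except the GC and length tests of the called genes and of the interferon list and the exchanges of libraries between groups, which were written before them; that exchanges decide nothing where 0 genes were called was set after, as was the use of the spread within HC serum for MAGED4B, once a first form of that test had been read as a decision. Genes picked after their values were seen show where L-Sep with flare serum moved HRGEC most. Among called protein-coding genes with a mean of at least 1 CPM, IGFBP1, which binds insulin-like growth factors and is a target of FOXO factors, rose from 1.25 ± 0.312 to 4.32 ± 0.903 CPM (SD, n = 5; log2 fold change 1.77, SE 0.295, edgeR adjusted p 0.000814). VAV3, an exchange factor that acts on the cytoskeleton, rose from 2.89 ± 0.627 to 7.03 ± 1.44 CPM (1.28, SE 0.221, adjusted p 0.00118). With GUCY1A2, the nitric oxide receptor subunit at 1.03, these genes were called in all 10 fits with 1 library left out. CSF2, a myeloid growth factor, rose by 1.35 (adjusted p 0.0272), a call lost without flare replicates 1, 2, 3 or 5 or L-Sep replicates 3 or 4 (0.0528 to 0.101). At the other end stood SERF1B, from 5.93 ± 4.23 to 1.73 ± 0.886 CPM (-1.76, SE 0.537, adjusted p 0.0394), lost without flare replicates 4 or 5 or L-Sep replicates 1, 3, 4 or 5 (0.0563 to 0.12), which has a near-identical copy, SERF1A, so its counts are uncertain. Below it in size came MT-CO2, a subunit of cytochrome oxidase, from 1743 ± 194 to 622 ± 363 CPM (-1.49), MT-ATP6 (-1.48) and MT-ND4, from 1338 ± 230 to 531 ± 220 CPM (-1.33).

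Aryl hydrocarbon receptor targets had mean list scores of 0.236 ± 0.083 with remission serum (SD, n = 4), 0.118 ± 0.09 with flare serum (n = 5) and 0.298 ± 0.054 with L-Sep (n = 5), against 0 ± 0.098 with HC serum (n = 5). Cell cycle scores were 0.088 ± 0.04 with remission serum, 0.118 ± 0.047 with flare serum and -0.117 ± 0.061 with L-Sep, against 0 ± 0.023 with HC serum. Over the 14 libraries without L-Sep, which belong to 3 groups, the mitochondrial score ran with log2 CPM of MEG3, a nuclear noncoding RNA, at a Pearson r of 0.773 (permutation p = 0.00055, adjusted 0.0022 over 4 relations; Spearman rho 0.82, permutation p = 0.00056). Without the 2 libraries farthest from the median, r was 0.704. For NEAT1, a scaffold RNA of nuclear bodies, r was 0.69 (permutation p = 0.00695, adjusted 0.00927; rho 0.714, permutation p = 0.00563) and 0.543 without those libraries. LENG8 (r 0.729, permutation p = 0.00218, adjusted 0.00436; rho 0.842; 0.718 without those libraries) and MALAT1 (r 0.608, permutation p = 0.0212, adjusted 0.0212; rho 0.745; 0.593 without them) ran the same way. These 4 RNAs were picked after their values were seen.

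The 5 genes called between flare and HC serum could reflect flare serum itself, a GC and length trend between libraries, or reads shared between near-identical genes. For the trend the called genes give no decision: the ratio of their median fold change after the correction to before was 0.841 (SE 0.107), and 2 of 5 were still called. For MAGED4B, shared reads are left open: the fold change of its counts summed with those of MAGED4 was a share of 0.216 of that of MAGED4B alone, but the sum ran from 81 to 1139 counts with HC serum, while MAGED4 stayed at 35 to 64, and MAGED4 was at 242 and 766 counts in flare replicates 3 and 4. An effect of flare serum on STK24, PIM3, PTMS and MMP24OS stays possible, and each of these calls was lost when any flare library was left out. For the genes called with L-Sep the GC and length trend is not favoured, with a ratio of 0.954 (SE 0.00941).

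Type I interferon scores differed between libraries with flare serum, at 2.10 and 1.67 in replicates 2 and 3 and -0.24 to 0.25 in the others, and L-Sep replicates 2 and 3 had 2.06 and 1.61. A serum donor shared by libraries of the same number might explain this, and the test gives no decision: 7 of 120 pairings of the numbers had a mean difference as small as the observed 0.239, a share of 0.0583 (exact). Over genes outside the interferon lists the real pairing had the highest sum of correlations of 120 (share 0.00833), and a shared culture day would give the same, so a shared donor stays open. The GC and length trend is not favoured, with a ratio of 1.1 after the correction to before for the interferon genes. Interferon in some flare sera could give the same pattern, and the labels hold nothing to test it with.

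Exchanging libraries between groups showed how often chance gives as many calls. Of 100 exchanges of the libraries of flare and HC serum, the real grouping included, 1 gave 5 or more genes, and the highest other count was 1. For L-Sep with flare serum against flare serum, 1 of 100 gave 1656 or more, and the highest other count was 671, when L-Sep replicate 5 changed places with flare replicate 3. For remission against HC serum and flare against remission serum, 100 and 100 of 100 gave at least the 0 genes called, which decides nothing because each exchange does, and the highest other counts were 5 and 0. For L-Sep with flare serum against HC serum, 2 gave 2170 or more, and the highest other count was 2677, with L-Sep replicate 5 in the place of HC replicate 3. For the number of gene lists called by camera chance cannot be excluded: 32 of 100 exchanges gave 8 or more lists for flare against HC serum, 8 gave 16 or more for L-Sep with flare serum against flare serum, and 26 gave 10 or more for remission against HC serum. For flare against remission serum 79 gave 4 or more, and for L-Sep with flare serum against HC serum 9 gave 16 or more. The exchanges do not test single lists. By the exact permutation test of scores, some lists differed between L-Sep with flare serum and flare serum, each at p = 0.00794, adjusted 0.0377. They were the cell cycle, mitochondrial, p53, lysosomal, YAP and SRF, angiogenesis, KLF2 and adhesion lists. No list passed it in the other comparisons. The lowest adjusted p of this permutation test against HC serum was 0.301 for flare, 0.302 for remission and 0.0503 for L-Sep with flare serum. The smallest unadjusted p that the test can give is 0.00794, so passing depends on how many lists reach that value. The cell cycle list reached it against HC serum for flare, remission and L-Sep with flare serum. Not passing therefore does not show that a list did not differ.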
